A study of Mus musculus with 14 samples.

How the data were processed

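Liver RNA of 6 floxed control mice and 8 mice with Mettl3 floxed and Alb-Cre was measured by total RNA sequencing. Per the labels, tissue was flash-frozen, RNA was extracted with Trizol, and libraries were made with a stranded total RNA kit of the Takara SMARTer Pico type. The strand setting used for counting was not stated. Per the submitters' processing notes, reads were quantified with kallisto on mm10 and tested with sleuth, with no versions given. The authors deposited 1 table of 75859 lines, which held 54446 genes, because a gene with several biotypes was listed once for each with the same values. These were reduced to 1 line per gene. For 27 genes the symbol had been turned into a date, and these were followed by their identifiers.

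The signal values that the authors deposited per library were normalised estimated counts per gene, that is, kallisto's estimated counts divided by 1 size factor per library. This was read from the values: among low values, 27.9% to 29.8% per library were whole multiples of the worth of 1 read (within 0.02 of a read, for values under 200 reads). The depth of each library, in estimated reads, was the sum of its values divided by that worth. The p-value and q-value columns were deposited by the authors from the sleuth Wald test, which covered 27865 genes. The change that the authors deposited was a natural log: it equalled the control mean minus the knockout mean of ln(value + 0.5), and the column named as a log2 fold change was the same number with its sign turned. Deposited changes were therefore not used as log2 values.

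The design assumed that values per library would be counts or TPM. They were neither, so the log-scale test of the design was used: limma 3.58.1 in R 4.3.3 with a trended prior variance on log2(value + 1), knockout minus control, with no covariate. Genes needed a value of at least 10 in at least 6 libraries, which left 23554 genes. P values were adjusted by Benjamini-Hochberg, and an adjusted p of at most 0.05 was called. Because the values follow depth, low values in the shallow libraries were the least precise, and no binomial interval was given since the values were not counts. The pipeline was tested on simulated data with known changes.

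The gene lists, the limma, camera and fry tests and the rule for naming genes were fixed before the data were examined, and the exact permutation test of lists was added afterwards. There were 34 lists: m6A factors, core clock, rhythmic liver genes, S phase, mitosis, ploidy-related cell-cycle genes, p53 targets, hepatocyte identity, fetal liver, cholangiocyte, stellate cell, Kupffer cell, lymphocyte, neutrophil, endothelial, erythroid, pancreatic acinar, interferon-stimulated, acute phase, lipogenesis, cholesterol, fatty acid oxidation, bile acid, pericentral, periportal, stress response, NRF2 targets, cytochromes P450, male-biased, female-biased, sex-chromosome markers, growth hormone axis, mitochondrially encoded and immediate early genes. Some genes were in more than 1 list, among them Alb, Cdkn1a, E2f1, Slco1a1 and Cyp7b1. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists. The alternatives were camera with an estimated correlation, fry, and an exact permutation test, two-sided, of the mean log2 over the list in each library. Named genes were Mettl3, every measured clock gene, the 3 called members of each list with the largest absolute change, or the member with the smallest p where none was called, and the 8 largest increases and 8 largest decreases. The last were taken among called genes with a mean above the median, without predicted genes and pseudogenes. Of the genes that the rule names 4 are not reported here, and the counts of the lists include them. Positions came from GENCODE M21 on GRCm38.

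Libraries were put into a Y-positive and an Xist-high class from Xist and the sum of Ddx3y, Kdm5d, Uty and Eif2s3y, since sex was not labelled. The alternatives planned were a threshold of 0.01, a minimum change of 1.5-fold, genes above the median value, no filter, a pseudocount of 0.1, the authors' q, their test with unshrunken variance, each library left out in turn, the replicate number as a block, and for lists a correlation of 0.05, ranks, the change itself, an estimated correlation and fry. The alternatives chosen after seeing the data were the Xist class as a covariate, each class alone, knockout libraries 3, 6 and 7 left out, a pseudocount of 0.5, voom weights, scaling to the sum outside ribosomal RNA, quantile normalization, log2 estimated reads as a covariate and the exact permutation test of lists. Results per transcript were left out because the table held genes.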

Results

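Total RNA was sequenced from the flash-frozen livers of 14 C57BL/6 mice at 5 weeks of age. The controls were 6 mice with a floxed Mettl3 gene, and the knockouts were 8 mice that also carried Alb-Cre, a recombinase driven by the albumin promoter of hepatocytes. Mettl3 encodes the catalytic subunit of the complex that writes the m6A mark on mRNA. Each gene had a normalised estimated count in each library, called its value here. The libraries held 11.1 to 33.8 M estimated reads (M, megareads), with a mean of 26.2 M (SD 8.14, n = 6) in controls and 20.01 M (SD 8.19, n = 8) in knockouts. The labels gave no sex, but the libraries fell into a pair of classes by sex-linked transcripts. Replicates 1 to 4 of both groups had Xist values of 29.6 to 60.3 and summed values of 4 Y-linked genes of 1749 to 3248 (Y-positive libraries). Control replicates 5 and 6 and knockout replicates 5 to 8 had Xist values of 6565 to 11123 and Y-linked sums of 186 to 292 (Xist-high libraries). The class ran with depth, at 29.2 M estimated reads (SD 3.47, n = 8) in Y-positive and 13.9 M (SD 3.07, n = 6) in Xist-high libraries. The comparison asked how liver RNA differs once Mettl3 is deleted in hepatocytes, and the series title names liver homeostasis, hepatocyte ploidy and circadian gene expression as its subjects.

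Mettl3 itself (ENSMUSG00000022160, a protein-coding gene at chromosome 14, 52294841 to 52305128 on the minus strand of GRCm38) fell from 223 ± 23.7 (SD, n = 6) in controls to 99.5 ± 15.7 (SD, n = 8) in knockouts. The log2 change was -1.17 (SE 0.12, limma adjusted p = 1.32e-05), and the ranges did not overlap, at 199 to 263 in controls and 76.9 to 122 in knockouts. The change was -1.25 in Y-positive libraries and -1.03 in Xist-high libraries, where it missed the threshold in the limma fit to those 6 libraries (adjusted p = 0.0717). The deleted exon was not given, and where the remaining signal came from was not tested. Of the 20 writers, readers and erasers of m6A, 5 rose, 1 fell (Mettl3) and 14 did not pass the test, with the same counts, 5 and 1, adjusted over the list alone. Ythdf2, a reader that promotes mRNA decay, rose from 458 ± 78.4 (SD, n = 6) to 1235 ± 219 (SD, n = 8), a log2 change of 1.43 (SE 0.13, limma adjusted p = 5.68e-06) seen in 8 of 8 knockout libraries. Rbm15, an adaptor of the writer complex, rose by 0.66. The other members that rose, Ythdf1 (0.57), Mettl16 (0.51) and Ythdc1 (0.29), were picked out after their values were seen. Mettl14, the partner of Mettl3 in the writer complex, had a log2 change of -0.08 that did not pass (limma adjusted p = 0.684) and was also picked out afterwards. The list as a whole did not pass the camera test (median 0.11, adjusted p = 0.0993). Its mean log2 was higher in 8 of 8 knockouts and passed in the exact permutation test, two-sided (adjusted p = 0.0175). With labels permuted only within the Xist classes the list did not pass (exact permutation adjusted p = 0.0518). It also passed by fry (adjusted p = 0.0205), with camera in Xist-high libraries (0.0333), scaled to equal sums (0.0323) and after quantile normalization (0.0182), but not in Y-positive libraries (0.369), without knockouts 3, 6 and 7 (0.417) or with an estimated correlation (0.610). The median was 0.05 without knockout 7 and 0.18 without knockout 5.

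Across 23554 genes tested, 2697 were higher and 2583 lower in knockouts, of which 758 and 577 changed at least 2-fold. Among protein-coding genes the counts were 2155 and 2200 of 16169. The largest increases under the naming rule were Gsta1 (log2 4.88), Cib3 (4.46), Serpinb1a (3.96), Ifi27l2b (3.79), Cyp2b10 (3.71), H19 (3.45), Rad51b (3.34) and Abcc4 (3.28). Cib3 (ENSMUSG00000074240, chromosome 8, 72204335 to 72212837, minus strand) went from 148 ± 107 (SD, n = 6) to 2609 ± 857 (SD, n = 8), with an SE of 0.46 and a limma adjusted p of 1.54e-05. The largest decreases were 7 major urinary protein genes, Mup15 (-8.57), Mup17 (-7.81), Mup12 (-7.15), Mup7 (-7.05), Mup9 (-6.80), Mup19 (-6.63) and Mup18 (-6.37), and Serpina1e (-6.15), which encodes a member of the alpha-1-antitrypsin family. Mup15 lost its call without knockouts 3, 6 and 7 (adjusted p = 0.0623), in Y-positive libraries (0.113) and with voom weights (0.174), and Mup18 (0.0524) and Mup19 (0.0537) lost theirs in Y-positive libraries. Over 21 Mup genes the median change was -5.91, against -4.79 within Y-positive and -5.17 within Xist-high libraries. Members of the Mup, Serpina1, Gst and Cyp2c families are similar enough to share reads, so how their reads were divided among copies was uncertain. Of 27865 genes tested in the authors' deposited table, 4760 passed a q value of at most 0.05, and 4543 of the 5280 genes called by limma passed there in the same direction. With the Xist class as a covariate, 5020 of the 5280 remained called. The balance of the calls depended on the scaling: knockout libraries summed to 19.1 M (SD 1.37, n = 8) and controls to 24.1 M (SD 2.43, n = 6). Scaled to equal sums outside ribosomal RNA, the median log2 change of all genes moved by 0.329, and 7833 genes were higher and 866 lower, so that 90.04% of the calls were higher, against 51.1% before. The log2 changes below are relative to the deposited size factors and were higher by about that shift under equal sums. Knockout libraries 3, 6 and 7 lay apart on the first principal component, at 61.5, 99.7 and 96.3 against -10.7 to 27.6 in the other knockouts. Of these, 6 and 7 also had the highest share of mitochondrial protein-coding RNA, 7.88% and 7.95%, against 2.86% to 5.49% in the other 12 libraries. Without these 3 libraries 2165 genes were higher and 2176 lower, and 3660 of the 5280 remained called.

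Clock genes moved in opposite directions. Arntl, the transcriptional activator also called Bmal1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand), rose from 68.9 ± 13.1 (SD, n = 6) to 222 ± 91.7 (SD, n = 8), a log2 change of 1.59 (SE 0.25, limma adjusted p = 0.000409). Nfil3, a repressor of the genes that PAR bZIP factors activate, rose by 1.21, and both genes lay above the control mean in 8 of 8 knockouts. Dbp, a PAR bZIP activator (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, plus strand), fell from 3164 ± 358 (SD, n = 6) to 1455 ± 402 (SD, n = 8), a log2 change of -1.16 (SE 0.17, limma adjusted p = 0.000266). Of the 22 measured members 9 fell, 2 rose and 11 did not pass. Those that fell included Bhlhe41 (-1.57), Ciart (-1.42), Tef (-1.09), Per2 (-0.91), Per3 (-0.85), Cry1 (-0.59) and Cry2 (-0.47), and each of these lay above the control mean in 0 of 8 knockouts. Among those that did not pass were Per1 (-0.63), Nr1d1 (-0.51), Hlf (-0.33), Nr1d2 (-0.30), Clock (-0.15), Bhlhe40 (-0.04), Rora (0.09), Csnk1d (0.10), Npas2 (0.31) and Csnk1e (0.32). Adjusted over the list alone, 2 rose and 11 fell. The list was lower in the camera test (median log2 -0.40, adjusted p = 0.00307, and adjusted p = 0.454 with an estimated correlation), and its mean log2 fell in an exact permutation test, two-sided (adjusted p = 0.00566, 0 of 8 knockouts above the control mean). Among 22 genes with rhythmic expression in liver, 10 fell, 2 rose and 10 did not pass, or 10 fell and 4 rose adjusted over the list alone. Upp2, a uridine phosphorylase, fell from 9963 ± 1915 (SD, n = 6) to 2258 ± 1735 (SD, n = 8), or by 2.49 on the log2 scale, and Alas1, the rate-limiting enzyme of heme synthesis, fell by 1.89. Mtnr1a, a melatonin receptor, rose by 1.97. This list was lower in the camera test (median -0.62, adjusted p = 0.000105) and stayed so with an estimated correlation (adjusted p = 0.0309). Scaled to equal sums, Cry1 (adjusted p = 0.2502), Cry2 (0.381), Per2 (0.0891) and Per3 (0.0625) no longer passed, and within Y-positive libraries Cry1 (0.124), Cry2 (0.114) and Per2 (0.0677) did not. Under equal sums the clock median was -0.07, and Rora (adjusted p = 0.00676), Csnk1d (0.0153) and Csnk1e (0.0179) passed as higher. The list did not pass among genes above the median value (adjusted p = 0.110). Single libraries decided some calls. Cry1 lost its call without control replicate 1 (adjusted p = 0.0580), 2 (0.0556), 3 (0.0570) or 6 (0.0581), and without knockouts 3, 6 and 7 together (0.127). Per1 passed without control 4 (0.0331), Hlf without control 6 (0.0468) or knockout 1 (0.0471), Nr1d1 without knockout 1 (0.0328) or 2 (0.0488), and Nr1d2 without knockout 6 (0.0341) or without knockouts 3, 6 and 7 (0.00231). Hlf also passed in the variant of the authors' test with unshrunken variance (adjusted p = 0.0443), and Npas2 ran from 0.18 without control 2 to 0.46 without control 1. The labels gave no time of day at collection.

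**Figure D1:**
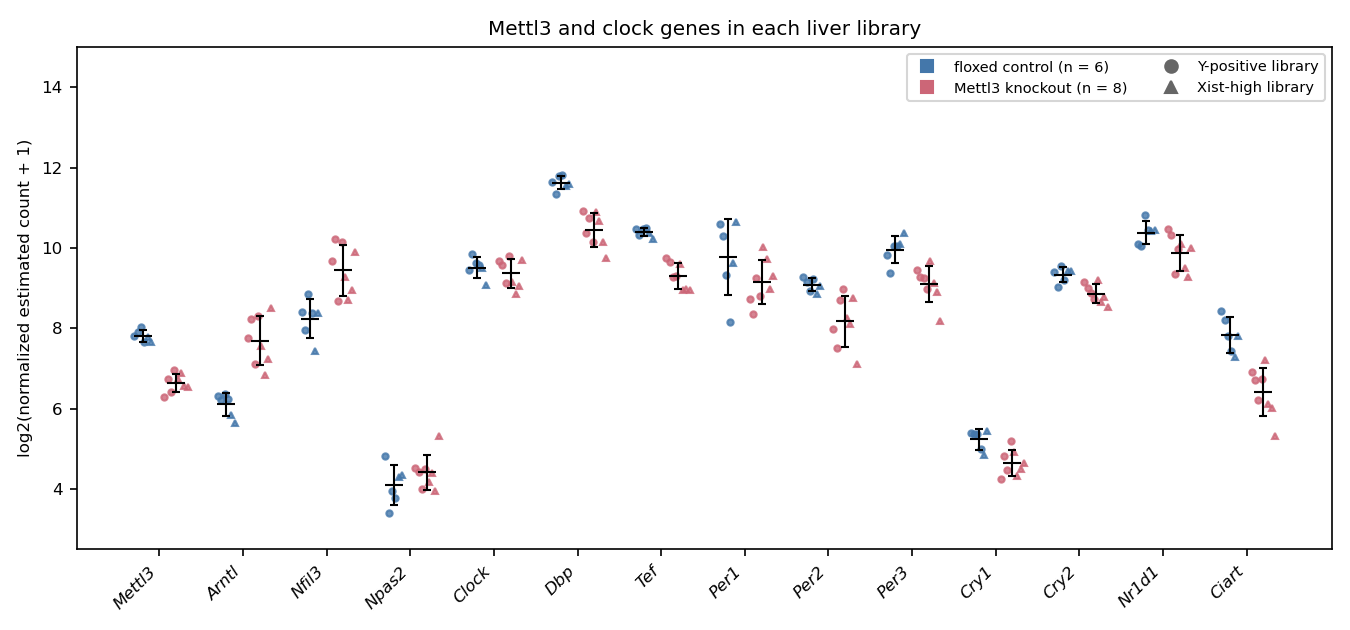
Log2 of the normalised estimated count plus 1 of Mettl3 and 13 clock genes in each of 6 control and 8 knockout libraries, with the group mean and SD as bars and the Xist class as the marker shape. Mettl3 fell by 1.17 and Dbp by 1.16 while Arntl rose by 1.59, and Npas2 (0.31) and Clock (-0.15) did not pass the test.

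Genes of DNA replication, mitosis and the p53 response were higher in knockouts. Of 20 S phase genes 11 rose and 0 fell, or 14 and 0 adjusted over the list alone. Mcm6, a subunit of the replicative helicase (ENSMUSG00000026355, chromosome 1, 128331590 to 128359664, minus strand), rose from 69.7 ± 21.03 (SD, n = 6) to 411 ± 241 (SD, n = 8), a log2 change of 2.38 (SE 0.34, limma adjusted p = 0.000185). Gins2, which acts with that helicase, rose by 2.28 and Uhrf1, which maintains DNA methylation through replication, by 2.14. Of 21 mitosis and cytokinesis genes 9 rose and 0 fell, or 18 and 0 adjusted over the list alone, with log2 changes of 1.89 for the cyclin Ccnb2 and 1.57 for the kinase Cdk1. Of 20 p53 targets 11 rose and 0 fell, or 11 and 1 adjusted over the list alone. Cdkn1a, an inhibitor of cyclin-dependent kinases (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), rose from 28.8 ± 10.3 (SD, n = 6) to 260.5 ± 215 (SD, n = 8), a log2 change of 2.71 (SE 0.50, limma adjusted p = 0.00141). Phlda3 rose by 2.63 and Btg2, an antiproliferative gene, by 1.98. Among 18 ploidy-related E2F and cell-cycle inhibitor genes 5 rose and 1 fell, with the same counts adjusted over the list alone, and those that rose included E2f1 (1.13) and the spindle checkpoint gene Mad2l1 (1.21). The camera test called all 4 lists higher, with adjusted p values of 3.64e-06 for S phase, 2.7e-05 for mitosis, 0.000303 for p53 targets and 0.0345 for the ploidy list. With an estimated correlation the adjusted p values were 0.454, 0.495, 0.454 and 0.507. Each list had a higher mean log2 in 8 of 8 knockouts than the control mean (exact permutation, two-sided, adjusted p of 0.00809, 0.0175, 0.0113 and 0.0175). When labels were permuted only within the Xist classes, the adjusted p values were 0.0162, 0.0567, 0.0393 and 0.0393, so mitosis did not pass. Knockouts 3, 6 and 7 had the highest Cdkn1a values, 481, 520.4 and 549.6, against 49.9 to 162 in the other knockouts and 18.3 to 41.1 in controls, and knockouts 6 and 7 were those with the highest mitochondrial share. Without them the median log2 changes went from 0.83 to 0.42 for S phase, from 1.10 to 0.51 for mitosis and from 0.60 to 0.36 for p53 targets, all still called, with Uhrf1 at 1.37, Ccnb2 at 1.19, Cdk1 at 1.03, Phlda3 at 1.34 and Btg2 at 1.29. The ploidy list lost its call without them (adjusted p = 0.269), without knockout 3 (0.0552), 6 (0.0543) or 7 (0.0680) alone, in Y-positive libraries (0.104), scaled to equal sums (0.0912), with log2 estimated reads as a covariate (0.0713) and at a preset correlation of 0.05 (0.116). Among the genes named here, Cdk1 (adjusted p = 0.0938), Uhrf1 (0.0699), Phlda3 (0.0689) and Mad2l1 (0.0594) did not pass within Y-positive libraries. The mitosis median was 0.64 in Y-positive and 1.67 in Xist-high libraries, which include knockouts 6 and 7. Mean log2 over that list was 7.11 and 6.73 in these, against 4.90 and 5.31 in Xist-high knockouts 5 and 8.

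Genes that define hepatocytes were lower. Of 23 hepatocyte identity genes 14 fell and 0 rose, or 17 and 0 adjusted over the list alone. Alb, which encodes albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand), fell from 185178 ± 35514 (SD, n = 6) to 88709.5 ± 20489.5 (SD, n = 8), a log2 change of -1.07 (SE 0.19, limma adjusted p = 0.00105). The transcription factor Foxa3 fell by 0.96 and the tyrosine-degrading enzyme Hpd by 0.93. The list was lower in the camera test (median log2 -0.65, adjusted p = 4.22e-07, and adjusted p = 0.454 with an estimated correlation) and in the exact permutation test, two-sided (adjusted p = 0.00809, 0 of 8 knockouts above the control mean). Genes of both liver zones fell. Of 21 pericentral genes 7 fell and 2 rose (9 and 2 adjusted over the list alone), among them Cyp2c54 (-3.94) and the sterol hydroxylase Cyp27a1 (-1.14). Of 18 periportal genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with Pck1, the gluconeogenic carboxykinase, at -1.42 and the aldehyde dehydrogenase Aldh1b1, the member that rose, at 1.68. Camera adjusted p values were 0.000454 for pericentral and 0.00275 for periportal genes, both with an adjusted p of 0.454 with an estimated correlation. After quantile normalization the hepatocyte identity list (median -0.16, adjusted p = 0.186), the periportal list (-0.32, adjusted p = 0.295), Alb (adjusted p = 0.0857), Hpd (0.198) and Pck1 (0.0707) did not pass, and the periportal list did not pass among genes above the median value (adjusted p = 0.0586). Without knockouts 3, 6 and 7 the medians were -0.37 for hepatocyte identity, -0.27 for pericentral and -0.40 for periportal genes, still called, and Hpd was -0.60, while Pck1 lost its call (adjusted p = 0.0541).

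Lipid synthesis genes were lower as well. Of 18 lipogenesis genes 11 fell and 0 rose, with the same counts adjusted over the list alone. Thrsp, a regulator of lipogenesis, fell from 9135 ± 5060.5 (SD, n = 6) to 1699 ± 1183 (SD, n = 8), a log2 change of -2.73 (SE 0.59, limma adjusted p = 0.00385). Srebf1, the transcription factor that drives fatty acid synthesis, fell by 1.89 and Fasn, fatty acid synthase, by 1.69. Of 22 cholesterol synthesis and uptake genes 7 fell and 0 rose, or 8 and 0 adjusted over the list alone, among them Idi1, an isoprenoid isomerase, at -1.27. Of 20 bile acid genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone. The transporter Slco1a1 went from 10471 ± 5765 (SD, n = 6) to 1407 ± 1709 (SD, n = 8), a log2 change of -3.48 (SE 0.71, limma adjusted p = 0.00269), and the oxysterol hydroxylase Cyp7b1 fell by 3.44, while the efflux pump Abcc4 rose by 3.28. Slco1a1 and Cyp7b1 are also members of the male-biased list below, so the 2 lists are not separate evidence. In Xist-high libraries alone Cyp7b1 was -1.93 and did not pass (limma adjusted p = 0.154), while Slco1a1 still passed. The camera test called these 3 lists lower, with medians of -0.85, -0.59 and -0.75 and adjusted p values of 4.22e-07, 8.99e-05 and 0.00204. With an estimated correlation the adjusted p values were 0.454 for lipogenesis, 0.563 for cholesterol and 0.454 for bile acid genes. In the exact permutation test, two-sided, lipogenesis and bile acid genes were lower in 8 of 8 knockouts (adjusted p = 0.00566 and 0.00809), and the cholesterol list did not pass there (0.125) or by fry (0.120). Bile acid genes did not pass after quantile normalization (adjusted p = 0.0755), and Idi1 (0.0765) and Thrsp (0.0586) did not pass within Y-positive libraries. Without knockouts 3, 6 and 7 the cholesterol median was -0.26, still called, and Idi1 was -0.82. That median was -0.34 in Y-positive and -1.14 in Xist-high libraries. Of 21 fatty acid oxidation genes 5 fell and 4 rose, or 7 and 5 adjusted over the list alone. Ppara, the receptor that activates this pathway, fell by 0.91 and the thioesterase Acot1 rose by 1.81. This list did not pass (camera adjusted p = 0.413), and its median (-0.11) and mean (0.18) differed in sign. The median turned to 0.0079 without control 5, and the list passed as lower in Xist-high libraries (adjusted p = 0.0359).

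Genes of glutathione conjugation and foreign compound metabolism moved both ways. Of 19 NRF2 target and glutathione genes 11 rose and 1 fell, with the same counts adjusted over the list alone. Gsta1, a glutathione transferase, went from 18.6 ± 17.0 (SD, n = 6) to 919 ± 1355 (SD, n = 8), a log2 change of 4.88 (SE 0.995, limma adjusted p = 0.00265), and Gstm3 rose by 2.84. The list was higher in the camera test (median 0.77, adjusted p = 0.000214, and adjusted p = 0.454 with an estimated correlation) and in the exact permutation test, two-sided (adjusted p = 0.00566, 8 of 8 knockouts above the control mean). Its median was 0.40 without knockouts 3, 6 and 7, still called. Of 22 drug-metabolising cytochromes P450 8 fell and 3 rose, or 10 and 3 adjusted over the list alone. Cyp2b10, a classical target of the receptor CAR, rose from 108 ± 139 (SD, n = 6) to 814 ± 401 (SD, n = 8), a log2 change of 3.71 (SE 0.62, limma adjusted p = 0.000644), while Cyp4f14 fell by 1.68. In Xist-high libraries alone Cyp2b10 was 1.92 and did not pass (limma adjusted p = 0.0521). The P450 list was lower in the camera test (median -0.76, adjusted p = 0.0306, and adjusted p = 0.454 with an estimated correlation). That call was lost without control replicate 5 (adjusted p = 0.0824) or 6 (0.0603), in Y-positive libraries (0.214), after quantile normalization (0.308) and in the exact permutation test (0.804). It was also lost among genes above the median value (adjusted p = 0.177), with ranks (0.0566), on the change itself (0.351) and at a preset correlation of 0.05 (0.116). Without knockouts 3, 6 and 7 its median was -0.40, still called, and Cyp4f14 was -0.99.

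Genes that male mouse livers express more highly than female livers were lower. Of 14 male-biased genes 5 fell and 0 rose, with the same counts adjusted over the list alone. Mup7, which encodes a urinary pheromone carrier (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475, minus strand), went from 192852 ± 182939 (SD, n = 6) to 1821.5 ± 2793 (SD, n = 8), a log2 change of -7.05 (SE 1.64, limma adjusted p = 0.00627). Mup1 fell by 5.92 and Mup3 by 3.74. These changes over all libraries include the unequal class shares, since 4 of 6 controls and 4 of 8 knockouts were Y-positive. The log2 change of the summed value of 21 Mup genes was -4.52 over all libraries. It was smaller within each class, at -3.74 in Y-positive and -4.32 in Xist-high libraries. The summed Mup value took 2.59% to 7.66% of all values in Y-positive controls. It took 0.0616% in Y-positive knockout 3 and 0.702% to 0.857% in Y-positive knockouts 1, 2 and 4. Within Y-positive libraries the mean log2 of the male-biased list was lower by -2.49 in knockouts (exact permutation, two-sided, p = 0.0286, the smallest that 70 splits allow). Within Xist-high libraries it differed by -0.80 (exact permutation p = 0.4, where 15 splits cannot reach the threshold). Over all 14 libraries the list was lower in the camera test (median -1.90, adjusted p = 0.0021, and adjusted p = 0.563 with an estimated correlation). It did not pass in the exact permutation test (adjusted p = 0.124), by fry (0.108), by camera in Xist-high libraries (0.362) or with log2 estimated reads as a covariate (0.0911). In an exact permutation restricted to within the Xist classes, the list differed by -1.65 in mean log2 and passed (adjusted p = 0.0393). Its median was -0.91 without knockouts 3, 6 and 7, with Mup1 at -3.74, Mup3 at -1.85, Mup18 at -3.34 and Mup19 at -3.72. Of 11 female-biased genes 0 rose and 0 fell by limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.703). Hao2 came closest, with a log2 change of 3.34 (limma adjusted p = 0.0500182), and passed without knockout 4 (0.0493), control 5 (0.0109) or control 6 (0.0112). It also passed among genes above the median value (adjusted p = 0.0364), with the class covariate (0.00607), in Y-positive libraries (1.05e-05), with voom weights (0.0290) and under equal sums (0.0244). By the authors' q it did not pass (0.0609), and in the variant of their test with unshrunken variance the adjusted p was 0.0473. The mean log2 of this list was 1.66 higher in knockouts within Y-positive libraries (exact permutation, two-sided, p = 0.0286) and differed by -2.15 within Xist-high libraries (exact permutation p = 0.0667, the smallest that 15 splits allow). Camera called it higher in Y-positive libraries (median 1.85, adjusted p = 0.00199) and lower in Xist-high libraries (median -1.78, adjusted p = 6.89e-09), and camera on the change itself called it higher over all libraries (7.36e-05). These camera values took a preset correlation of 0.01, where the correlation estimated over all libraries was 0.81. They treat the genes as nearly independent and do not measure the spread between animals. Over all libraries the camera adjusted p with the estimated correlation was 0.942. Of 15 growth hormone and insulin-like growth factor genes 4 fell and 0 rose, with the same counts adjusted over the list alone: Igfbp2 (-1.57), Igf1 (-1.20), Igfbp4 (-0.90) and the growth hormone receptor Ghr (-0.69), the last picked out after its value was seen. That list was lower in the camera test (median -0.15, 0.18 when scaled to equal sums, adjusted p = 0.042, and adjusted p = 0.454 with an estimated correlation), and its call was lost without any of knockouts 3, 4 and 6 and controls 3, 5 and 6 (adjusted p of 0.0515, 0.0650, 0.0665, 0.0626, 0.0523 and 0.0964), without control 3 with a median of -0.09. It was also lost without knockouts 3, 6 and 7 together (adjusted p = 0.0985), in Y-positive libraries (0.124), after quantile normalization (0.378), among genes above the median value (0.235), with ranks (0.0864), on the change itself (0.171), at a preset correlation of 0.05 (0.116) and in the exact permutation test (0.106). The list did pass in the exact permutation within the Xist classes (mean log2 difference -0.26, adjusted p = 0.0393). Its median was -0.27 in Xist-high libraries and -0.26 with log2 estimated reads as a covariate. Igfbp4 did not pass after quantile normalization (adjusted p = 0.0915), where Igf1 was -0.77. Of the 5 sex-chromosome markers 0 rose and 0 fell by limma, also adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.546), and Eif2s3y had a log2 change of -1.24 (limma adjusted p = 0.427). Within Y-positive libraries Eif2s3y (-0.73, adjusted p = 0.0157) and the list (camera adjusted p = 0.0221) passed as lower, as did Eif2s3y with the class covariate (-0.56, adjusted p = 0.0332).

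**Figure D2:**
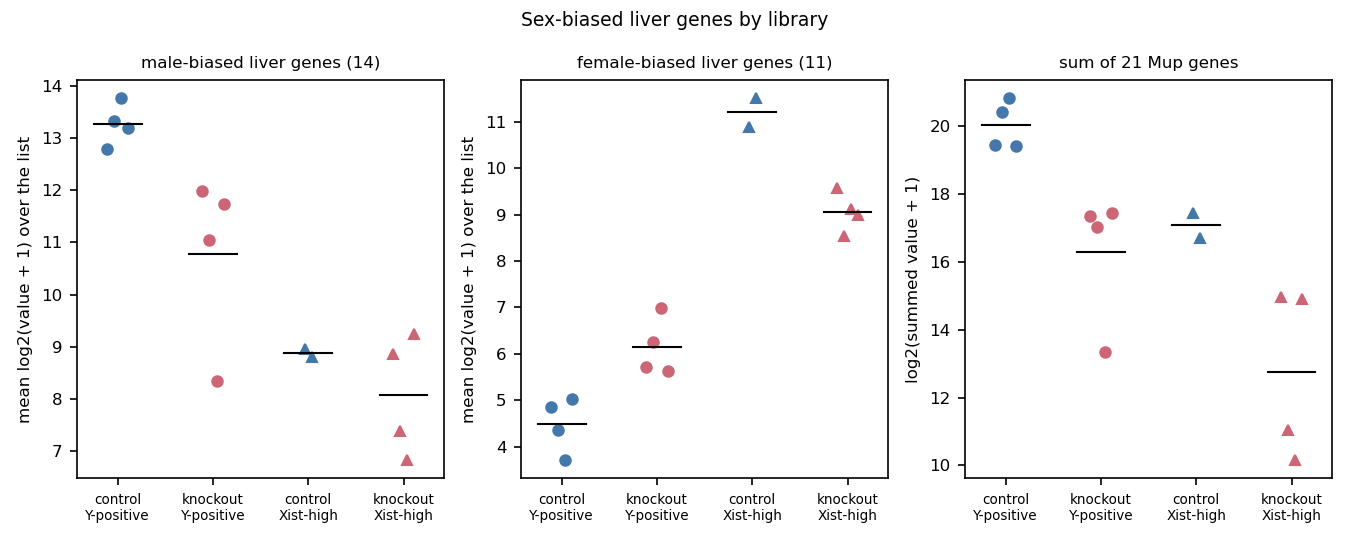
Mean log2 of the value plus 1 over 14 male-biased genes and 11 female-biased genes, and log2 of the summed value of 21 Mup genes, per library, by group and Xist class, with group means as lines (vertical axes do not start at 0). Within Y-positive libraries the knockouts differed from the controls by -2.49 for male-biased genes and by -3.74 for the Mup sum.

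Lists of other liver cell types were tested in the same way. Of 14 cholangiocyte and progenitor genes 4 rose and 0 fell, with the same counts adjusted over the list alone. Sox9, a transcription factor of bile duct cells, rose from 94.5 ± 33.6 (SD, n = 6) to 302 ± 85.9 (SD, n = 8), a log2 change of 1.70 (SE 0.26, limma adjusted p = 0.000304), and the tight junction gene Cldn4 rose by 2.60. This list was higher in the camera test (median 0.49, adjusted p = 0.00733, and adjusted p = 0.502 with an estimated correlation). Its call was lost in Y-positive libraries (adjusted p = 0.0724), when scaled to equal sums (0.0610) and without knockouts 3, 6 and 7 (0.138, where Cldn4 was 1.37 and Sox4 0.82), and without knockout 7 alone the median was 0.32. Of 14 fetal liver genes 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. The imprinted RNA H19 went from 37.5 ± 25.5 (SD, n = 6) to 617 ± 574 (SD, n = 8), a log2 change of 3.45 (SE 0.75, limma adjusted p = 0.00426), and Sox4 rose by 1.80. The fetal list did not pass (camera adjusted p = 0.0993), and its call was gained without knockout 2 (0.0471) and on the change itself (1.6e-05). Within Y-positive libraries Cldn4 (adjusted p = 0.128), H19 (0.0942) and Sox4 (0.141) did not pass, and Cldn4 did not pass with voom weights (0.0674). Of 17 endothelial genes 6 fell and 0 rose, or 7 and 0 adjusted over the list alone, with the sinusoidal lectin Clec4g at -0.54 (limma adjusted p = 0.00649). The endothelial median was -0.27 and turned to 0.07 when scaled to equal sums, where Clec4g did not pass (adjusted p = 0.217). The camera adjusted p was 0.000454, and the adjusted p was 0.454 with an estimated correlation, 0.0906 in Xist-high libraries and 0.0515 on the change itself. Of 20 Kupffer cell and macrophage genes 3 rose and 0 fell, also adjusted over the list alone: Mmp12 (2.33), the lipid receptor Trem2 (1.09) and the monocyte chemokine receptor Ccr2 (0.88). That list did not pass (camera adjusted p = 0.0993) but did without knockout 2 (0.0154), knockout 4 (0.0245) or control 4 (0.0493), in Xist-high libraries (0.00246), after quantile normalization (0.0408) and on the change itself (0.00595). Trem2 did not pass without knockouts 3, 6 and 7 (adjusted p = 0.0825), where Mmp12 was 1.46 and Ccr2 0.49. Within Y-positive libraries Trem2 (adjusted p = 0.217) and Ccr2 (0.160) did not pass.

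The stellate cell list had 1 gene that rose of 20 and 0 that fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.462). By limma 0 of 16 lymphocyte, 0 of 4 neutrophil and 0 of 9 erythroid genes passed, also adjusted over the lists alone, and 1, 1 and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.202, 0.407 and 0.413). Closest were Cd79b (-0.62, limma adjusted p = 0.107), Cxcr2 (0.43, 0.121) and Klf1 (-0.73, 0.0586). Cxcr2 passed under equal sums (adjusted p = 0.0127), and Klf1 without knockout 1 (0.0443), 2 (0.0374) or 5 (0.0422) or control 2 (0.0440), among genes above the median value (0.0437) and after quantile normalization (0.0458). By the authors' q Klf1 did not pass (0.0586), and in the variant of their test with unshrunken variance the adjusted p was 0.0454. Of 4 pancreatic acinar genes 1 fell and 0 rose, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.777, and 0.0445 on the change itself). Mean log2 over this list was 10.41 in knockout 4 and 4.22 to 6.56 in the other libraries. Its median was 1.31, and 0.50 without knockout 4, where the camera test pointed down (adjusted p = 0.762). The member that fell, Cela1 (-1.52, limma adjusted p = 0.0405), lost its call without any of knockouts 1, 2, 3, 5, 6, 7 and 8 or controls 1, 2, 3 and 4 (adjusted p from 0.0526 to 0.0853). It also lost it without knockouts 3, 6 and 7 (0.213), in Y-positive libraries (0.242), under equal sums (0.0630) and with log2 estimated reads as a covariate (0.106). Of 26 interferon-stimulated genes 5 rose and 0 fell, also adjusted over the list alone. Oasl1, an oligoadenylate synthetase-like gene, rose from 124 ± 32.8 (SD, n = 6) to 613 ± 155 (SD, n = 8), a log2 change of 2.30 (SE 0.20, limma adjusted p = 3.29e-06), and Ifi47 (0.98) and Isg15 (0.94) rose. The interferon list did not pass (camera adjusted p = 0.057) but did without knockout 2 (0.00600), 4 (0.0138), 7 (0.0468) or 8 (0.0307) or control 1 (0.0459) or 6 (0.0480), in Xist-high libraries (0.0416), with no filter on low values (0.0299) and after quantile normalization (0.0408). Of 18 acute phase and inflammation genes 2 rose and 2 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.709). C-reactive protein, Crp, fell by 2.06 and the iron-binding lipocalin Lcn2 rose by 1.79, and the list's median (-0.10, or 0.07 without control 6) and mean (0.02) differed in sign. Of 19 stress response genes 3 rose and 4 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.948). The chaperone Hspa5 rose by 1.07 and Herpud1, which acts in disposal of misfolded proteins, fell by 1.32, and the median (0.07) was positive where the test pointed down. Of 15 immediate early genes 2 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.856), with Myc at 1.94 and the heat shock gene Hspa1b at -1.48. Without knockouts 3, 6 and 7 Myc did not pass (adjusted p = 0.0567) and Crp was -1.31, and Myc did not pass in Y-positive libraries (0.0904). By limma 0 of 15 mitochondrially encoded genes passed, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.783), with a median of -0.03 and a mean of 0.01. The list passed as lower within Y-positive libraries (median -0.35, adjusted p = 0.0258) and as higher after quantile normalization (median 0.42, adjusted p = 0.0177), and mt-Nd1 passed as higher under equal sums (1.02, adjusted p = 0.0129) and after quantile normalization (1.34, 0.0105).

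Over the lists, 15 named genes lost their call when some library was left out, among them Cry1 and Cela1, and the other 13 had these log2 changes and limma adjusted p values. The endothelial genes Gpr182 (-0.47, 0.0330) and Oit3 (-0.55, 0.0304) lost their calls without any one of 10 and 7 of the 14 libraries. The cholesterol enzyme Fdps (-1.19, 0.0437) and the stress response gene Trib3 (1.68, 0.0496) did so for 9 each, and the cholangiocyte marker Epcam (1.31, 0.0422) and the cytochrome Cyp2c55 (1.62, 0.0354) for 8 each. The chemokine Ccl2 (1.87, 0.0353) did so for 7, the immediate early gene Fos (0.85, 0.0320) for 5 and the kinase Pdk4 of the fatty acid oxidation list (2.13, 0.0280) for 4. Tspan8 of the fetal list (1.49, 0.0263) and the periportal Cyp2f2 (-1.53, 0.0292) did so for 3 each, and the cyclin Ccnb1 (1.78, 0.0205) and the pericentral Cyp2a5 (1.01, 0.02001) for 1 each. The highest adjusted p values were 0.0695 for Gpr182, 0.0682 for Oit3, 0.0913 for Fdps, 0.0945 for Trib3, 0.1002 for Epcam, 0.0849 for Cyp2c55, 0.0729 for Ccl2, 0.0755 for Fos, 0.0564 for Pdk4, 0.0619 for Tspan8, 0.0660 for Cyp2f2, 0.0510 for Ccnb1 and 0.0525 for Cyp2a5. Of the 13, 10 did not pass without knockouts 3, 6 and 7 together: Ccnb1 (adjusted p = 0.0743), Tspan8 (0.138), Epcam (0.186), Oit3 (0.0933), Gpr182 (0.144), Ccl2 (0.0925), Fdps (0.134), Cyp2a5 (0.0601), Cyp2c55 (0.164) and Fos (0.129). Pdk4 (1.08), Cyp2f2 (-0.66) and Trib3 (0.65) still passed with smaller changes. Within Y-positive libraries 10 did not pass: Ccnb1 (adjusted p = 0.148), Tspan8 (0.121), Epcam (0.2202), Ccl2 (0.168), Fdps (0.294), Pdk4 (0.0873), Cyp2f2 (0.0733), Trib3 (0.0711), Cyp2c55 (0.818) and Fos (0.318). Cyp2c55 was 0.18 there and 3.64 in Xist-high libraries. Under equal sums Oit3 (adjusted p = 0.323), Gpr182 (0.487) and Fdps (0.0857) did not pass, and with the class covariate Epcam (0.0502), Fdps (0.0539) and Trib3 (0.0597) did not. After quantile normalization Epcam (adjusted p = 0.0653), Gpr182 (0.0516), Ccl2 (0.0619), Fdps (0.1098), Cyp2f2 (0.0716), Trib3 (0.0611) and Fos (0.12) did not pass. With voom weights Epcam (adjusted p = 0.0669), Ccl2 (0.0759), Pdk4 (0.0705), Trib3 (0.0859), Cyp2c55 (0.0765) and Fos (0.0584) did not, and with log2 estimated reads as a covariate 10 did not, all but Gpr182, Oit3 and Ccnb1. Trib3 did not pass by the authors' q (0.0598) or with a pseudocount of 0.1 (0.0506) either.

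Altogether 34 lists were tested, of which camera called 6 higher and 12 lower. Of these 18, 1 stayed called with an estimated correlation, the list of rhythmic genes.

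**Figure D3:**
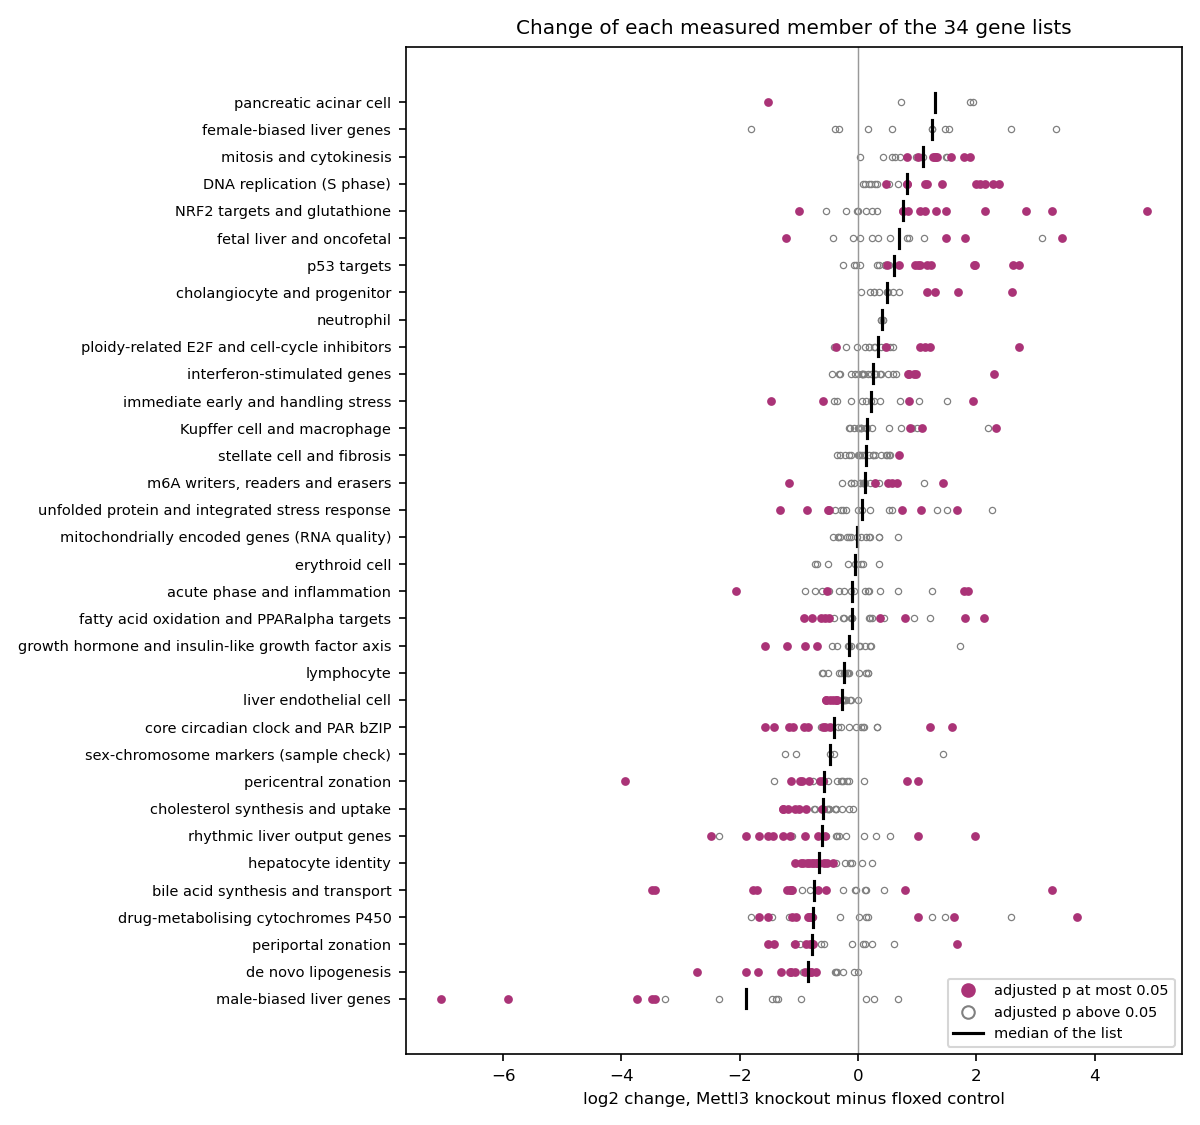
Log2 change, knockout minus control, of every measured member of 34 gene lists, filled where the adjusted p was at most 0.05, with the list median as a bar. Medians ran from -1.90 for male-biased genes to 1.31 for pancreatic acinar genes, the latter 0.50 without knockout 4. Medians of the endothelial and growth hormone lists, among others, turned positive when libraries were scaled to equal sums.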

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

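The tests with the Xist class as a covariate, of male-biased genes within Y-positive libraries and against hepatocyte identity, and of Npas2 were chosen only after the results were seen. Of 232 gene and group pairs tested for a library far from the rest of its group, 6 had one. The rule's 95% level gives about 1 in 20 by construction, a rate that was not measured here. Knockout 8 had an Npas2 value of 39.2 (other knockouts 14.5 to 22.0) and a Bhlhe40 value of 1229.5 (1735 to 2194 in the others). Knockout 4 had a Cela1 value of 1087 (59.1 to 136). Control 2 had a Fdps value of 4335 (other controls 9379.7 to 12797) and a Cyp4f14 value of 4527 (6281 to 7484). Control 5 had an mt-Nd1 value of 76974 (49454 to 53445).

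The knockout change differed between Y-positive and Xist-high libraries for 13 genes by an interaction term in limma, 11 with the higher change in Y-positive libraries. As Y-positive minus Xist-high log2 changes these were Cyp2c39 (10.75), A1bg (6.59), Cyp3a41a (6.16), Zbed4-ps2 (5.87), Hao2 (4.50), Gm15612 (3.75), Cyp2a22 (3.74), Cyp3a44 (3.54), Cyp2c38 (3.53), Gm6135 (3.03), Slc22a27 (2.99), Gstp1 (-2.70) and Gm17122 (-3.05). At an unadjusted p under 0.05 there were 1395 of 23554 genes, where chance alone gives a share of about 0.05. By camera on the interaction 13 lists differed. The difference of the median changes was 3.63 for female-biased genes, -1.84 for male-biased genes, -1.04 for mitosis, 0.80 for cholesterol, -0.61 for sex-chromosome markers, 0.50 for cytochromes P450, -0.46 for S phase, -0.43 for mitochondrially encoded genes, 0.42 for pericentral genes, 0.31 for lipogenesis, -0.20 for endothelial genes, -0.14 for m6A factors and 0.048 for fatty acid oxidation. With an estimated correlation 1 of the 13 stayed called, the female-biased list (adjusted p = 0.00779). Xist-high controls were 2 libraries, so each of these differences rests on them, and sex could not be separated from depth.

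Of 100 splits of the 14 libraries into groups of 6 and 8, the real one included, only the real split gave 2697 higher genes (highest other 538). It alone also gave 2583 lower genes (highest other 418). This argues against chance, although 100 splits can show no share under 1 in 100. Within Y-positive libraries only the real one of 35 splits gave 3694 genes (highest other 3). That argues the same way, at the lowest share that 35 splits allow. With the Xist class as a covariate 95.1% of the calls remained, and with log2 estimated reads as a covariate 81.9%, which argues against class and depth as the whole cause. When libraries were scaled to the sum outside ribosomal RNA 67.5% remained, and no spike-in was there to tell which scaling holds, so how many calls follow from the scaling stays open. For the number of lists, 11 of 100 splits gave as many as the real 18 (highest other 24), and chance was not excluded.

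The lower male-biased genes were weighed against 3 technical explanations. Unequal shares of the classes were argued against by the difference of -2.49 in mean log2 within Y-positive libraries. Reads shared among Mup copies were argued against by the Mup sum, which differed by -3.74 there. A lower share of hepatocyte RNA was argued against by the list's fall beyond that of hepatocyte identity genes, -1.98 (exact permutation, two-sided, p = 0.0286 for each of the 3, the smallest 70 splits allow). The sizes lean on knockout 3, whose mean log2 of the list was 8.35. Y-positive knockouts 1, 2 and 4 had 11.04 to 11.98, and Y-positive controls 12.78 to 13.77. Depth was not among these 3 explanations. With log2 estimated reads as a covariate over all libraries, the list lost its camera call. Depth ran with the Xist class, and with the class itself as the covariate the list kept its call (camera adjusted p = 0.00187). Mean depth in Y-positive libraries was 27.4 M estimated reads in knockouts and 31.0 M in controls. Knockout 1 had 30.9 M and a list mean of 11.98, while controls 1 and 4 had 26.4 M and 30.5 M with 12.78 and 13.20. Depth alone therefore did not order these libraries, though knockout 4 had the lowest depth, 24.3 M (list mean 11.74). A lower male-biased program in livers without Mettl3 may be a biological effect, which remains a hypothesis from the same data. How far depth enters and whether the program differs between the sexes are open.

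The clock genes moved in opposite directions, which a change of scaling alone does not give. With the Xist class as a covariate 100% of the called clock genes remained, which argues against unequal classes. A different time of day at collection could raise Arntl and lower Dbp together, and Npas2, which peaks with Arntl, had a log2 change of 0.31 that did not pass (limma adjusted p = 0.406), or 0.49 without knockouts 3, 6 and 7. That value does not decide, and the labels gave no time, so an effect of Mettl3 loss and a shift in collection time cannot be told apart.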

How the results depend on the processing

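The alternatives chosen after seeing the data were the Xist class as a covariate, each class alone, knockouts 3, 6 and 7 left out, a pseudocount of 0.5, voom weights, the sum outside ribosomal RNA, quantile normalization, log2 estimated reads as a covariate and the permutation test of lists. Mettl3 was lower and passed under every alternative run except in Xist-high libraries alone (-1.03), where fewer libraries were fitted. Of 110 named genes, 1 or fewer lost their call with a pseudocount of 0.1 or 0.5 or with the authors' q, 3 with the class covariate, 4 at a minimum of 1.5-fold, 8 with voom, 9 with scaled sums, 11 with log2 reads, 11 after quantile normalization, 12 with no filter, 16 without knockouts 3, 6 and 7, 26 at a threshold of 0.01, 29 in Y-positive and 83 in Xist-high libraries alone. Mettl3, which lost its call in Xist-high libraries alone, is not in these counts of lost calls. Leaving out each library in turn gave 2189 to 2863 higher and 2039 to 2792 lower genes. The edgeR count model of the design and count-based normalizations were not run. The voom alternative was fitted to the values divided by the worth of 1 read. Alternatives per transcript gave no values, because the table held genes. In simulated data 17.9% of 1.5-fold, 43.3% of 2-fold and 81.8% of 4-fold changes were recovered. The simulation gave these folds to 200 genes, where the data had 5280 calls. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so these rates do not give the sensitivity in the data. Except where named, the cause of a change was not tested.

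At a threshold of 0.01 there were 1311 higher and 1358 lower genes, and at least 1.5-fold were 1371 of the lower genes, both fewer by construction. In Y-positive libraries alone 1740 were higher, and in Xist-high libraries alone 172 were higher and 47 lower, with fewer libraries. Scaled to the sum outside ribosomal RNA, 7833 were higher and 866 lower, since knockout libraries had the lower sums. By camera with an estimated correlation 0 lists were higher and 1 lower, on the change itself 10 were higher, and after quantile normalization 10 were higher and 7 lower.

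Most values that changed sign were near 0. For genes these were, in Y-positive libraries, Csnk1d (-0.047) and Bhlhe40 (0.11); in Xist-high libraries, Hao2 (-0.030); without knockouts 3, 6 and 7, Clock (0.072); and with scaled sums, Hlf (0.0045), Nr1d2 (0.043), Clock (0.19) and Bhlhe40 (0.30). Bhlhe40 was 0.13 after quantile normalization and 0.024 with log2 reads, where Eif2s3y was 0.24.

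For lists the sign is that of the test, and the value is the median change. Among genes above the median value these were lymphocyte (-0.010), stress response (0.031) and mitochondrially encoded genes (-0.025). With the class covariate the stress response was 0.030. In Y-positive libraries it was -0.082 and immediate early genes were 0.19. In Xist-high libraries erythroid genes were 0.36, female-biased -1.78, sex-chromosome markers 0.18 and mitochondrially encoded genes 0.074. Without knockouts 3, 6 and 7 stellate genes were 0.036, stress response 0.019 and immediate early genes -0.18. With scaled sums pancreatic genes were 1.61, female-biased 1.58 and immediate early genes 0.55. After quantile normalization acute phase genes were -0.18, fatty acid oxidation 0.084, stress response 0.15 and mitochondrially encoded genes 0.42. With log2 reads stellate genes were 0.056, female-biased -0.89, sex-chromosome markers 0.24 and immediate early genes 0.17. The stress response was 0.068 with ranks, with the change itself, by fry and in the permutation test. Fatty acid oxidation was -0.11 with the change itself and in the permutation test, where acute phase genes were -0.095 and mitochondrially encoded genes -0.025.

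Leaving out each library in turn, Bhlhe40 ran from -0.10 to 0.054, 15 named genes lost a call and 6 gained one without some library. List medians ran from -0.19 to 0.16 for erythroid, -0.18 to 0.065 for acute phase, -0.15 to 0.0079 for fatty acid oxidation, 0.50 to 1.58 for pancreatic, 0.0061 to 0.17 for stress response, 0.54 to 2.11 for female-biased, -0.13 to 0.052 for mitochondrially encoded and 0.072 to 0.32 for immediate early genes.

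With the replicate number as a block (replicate block), 2037 genes were higher and 1917 lower. Of the 5280 calls 3593 remained, and 11 named genes lost their call, among them Cry1 (adjusted p = 0.132), Cry2 (0.0528), Trem2 (0.0817), Ccr2 (0.0707) and Mup15 (0.0520). The ploidy list was lost (0.0527), and the fetal (0.0448) and interferon (0.0128) lists were gained. The numbers were not taken to pair the samples: correlations of same-numbered deviations were 0.0707 to 0.228, with 1 of 6 under 0.1, and 2 of the 6 controls correlated best with the knockout of their own number. Bhlhe40 was then 0.071, the stress response -0.0030 and immediate early genes 0.14.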

Other observations

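Of 16 gene families, all chosen after seeing the data, camera called 7, none of them with an estimated correlation, and those not called were the Gst, Sult, Cyp3a, Cyp4a, Slc22, histone, collagen, small nucleolar RNA host, and claudin and keratin families. Proteasome genes were lower: 27 of 40 fell and 1 rose, with a median log2 change of -0.46, among them Psmb6 (-0.68), Psmd9 (-0.67) and Psma7 (-0.66). The median was -0.12 when libraries were scaled to equal sums and -0.34 after quantile normalization (camera adjusted p = 3.87e-11, and adjusted p = 0.3796 with an estimated correlation). Of 85 nuclear genes of the respiratory chain 29 fell and 5 rose, with a median of -0.23 that turned to 0.11 when scaled to equal sums and was -0.35 in Y-positive libraries, -0.13 in Xist-high libraries and -0.045 after quantile normalization (camera adjusted p = 9.3e-07, and adjusted p = 0.482 with an estimated correlation). Of 78 ribosomal protein genes 5 rose and 0 fell, with a median of 0.32, at 0.13 in Y-positive and 0.53 in Xist-high libraries, 0.66 when scaled to equal sums and 0.58 after quantile normalization (camera adjusted p = 0.000213, and adjusted p = 0.558 with an estimated correlation). Over all genes 2697 of 23554 rose, a larger share, so the count of ribosomal protein genes shows no excess of rises. Of 21 Mup genes 19 fell, and of 18 Ugt genes, which encode glucuronosyltransferases, 5 fell and 0 rose, with a median of -0.92, at -0.43 in Y-positive libraries, -0.58 when scaled to equal sums and -0.61 after quantile normalization. Of 141 small nucleolar RNAs 9 fell (6.38%) and 1 rose, with a median of -1.07. Over all genes 2583 of 23554 fell, a larger share, so the count shows no excess of falls.

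The tests of differences between classes were chosen only after the result was seen, and the test of long exons before. Long internal exons are one place where mRNA carries m6A. A hypothesis was therefore that genes whose longest internal exon has at least 400 bases rise relative to others. Matched on mean value and transcript length, their median log2 change was 0.0449 higher (exact permutation, two-sided, p = 0.00233 over 3003 splits), and 0.0441 within classes (exact permutation p = 0.00476). In 7 of 8 knockouts the difference lay above the highest control. Of 3143 such genes 16.2% rose and 8.88% fell, against 12.6% and 14.8% of 13003 others. The others included genes without an internal exon, and the lengths of first and last exons did not enter the split. The result was consistent with the hypothesis, the shift was small, and m6A was not measured.

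The classes differed less in female-biased genes in knockouts, a contrast that is the class interaction itself and so no further test of it. For female-biased genes the difference of Xist-high minus Y-positive mean log2 was 6.72 in controls and 2.91 in knockouts, smaller by 3.81 (exact permutation within classes, p = 0.000952, the smallest that 1050 permutations allow). Of this, 1.66 was a higher level in Y-positive knockouts and -2.15 a lower level in Xist-high knockouts. For male-biased genes it was -4.39 and -2.70, a difference of -1.69 that did not pass (exact permutation p = 0.289). Both rest on 2 Xist-high control libraries, depth was not separated from class, and the cause stays open. The permutations shuffled control and knockout labels within each class. Their p values therefore assume no knockout effect in either class, and do not test whether the classes changed equally.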
